A study of Rattus norvegicus with 6 samples.

How the data were processed

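The data are polyadenylated RNA-seq libraries of primary rat nucleus pulposus cells, 3 untreated and 3 given 10 µM bradykinin. Groups and replicate numbers were taken from the sample labels, in which the treated samples are titled B2R, a short name of the B2 receptor, while their treatment label names bradykinin. The treatment label was followed, and what the title refers to is not given in the sources used here. How long the cells were treated is not given in the sources used here. Per the labels' protocols and the series design text, mRNA was selected with oligo-dT beads, fragmented and copied with random hexamers, and sequenced in pairs on an Illumina instrument. The labels do not say that the kit keeps strand, so reads of a gene and an overlapping antisense gene cannot be told apart.

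The deposited table holds whole-number counts per Ensembl gene, not normalized. Per the submitters' processing notes, the authors used fastp 0.23.2, HISAT2 2.2.1, Bowtie2 2.4.5, SAMtools, RSEM 1.3.3 and DESeq2 1.34.0, with the genome build Rnor_6.0. The series design text gives trimming to fastp, alignment to HISAT2 and quantification to RSEM. RSEM estimates need not be whole, and how the counts became whole numbers is not given in the sources used here. RSEM also shares out reads among similar genes by estimate, so values of ribosomal protein genes and of other families with near-identical copies are uncertain, as are those of overlapping genes. No row without a gene was present.

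The table lists 17139 genes, of which 379 had 0 counts in every library. Symbols were taken from the Entrez identifiers of the deposited table, looked up in a RefSeq gene table of the GRCr8 assembly. A single identifier named 14862 genes, and 38 with several identifiers had a single symbol among them. A further 172 had several symbols and kept all of them, 13 mitochondrial genes were named by the table's KEGG column, and 2054 had no symbol. Another 27 rows shared a symbol with a row of more counts and had their identifier added to it. That assembly differs from the build of the files, so no coordinates are given, and its gene spans served only to rank genes by genomic length. A span was found for 92.6% of the tested genes. Transcript length and GC content were not used here.

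Total counts per library ranged from 12883067 to 15462764, and 14724 to 15027 genes had at least 1 count in a library. CPM divide each count by the library's count over tested genes times its TMM factor. Groups were compared with edgeR 4.0.16 (R 4.3.3): genes were kept by filterByExpr, libraries were scaled by TMM, and a quasi-likelihood F test (two-sided) gave p-values, adjusted by the Benjamini-Hochberg method over 12413 genes. A gene counted as changed at an adjusted p of 0.05 or less, the false discovery rate the study itself names, and an absolute log2 fold change of 1 or more marked changes of 2-fold or more. SE of a log2 fold change is the change divided by the root of its F. The interval of the Cers1 ratio is an exact binomial (Clopper-Pearson) interval at 95%. A count of 0 in a library allows up to 3 counts. Such intervals and limits cover counting error only.

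Fixed before the data were examined were the tests, the alternatives, 29 gene lists and the rule for naming genes. The 23 lists with 5 or more tested members were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided and adjusted over those lists. None of the 7 calls held with the correlation estimated from the data or with fry, a test of whether a list's genes move on balance one way. The edgeR p-values of members were also adjusted by Benjamini-Hochberg over each list alone, with no correction for the number of lists. The genes named are the receptors Bdkrb1 and Bdkrb2, and 12 matrix, senescence and cytokine genes named in advance. Also named are up to 4 members with the smallest p of each list described and, since under 10 genes passed, the 10 genes with the smallest p. Had more passed, the 10 highest and 10 lowest changed genes with average log2 CPM of 2 or more, a symbol and no overlap between groups would have been named. That part was applied to the 5 libraries. Acta2, Tagln, Adamts12, Pgk1, Pkm, Cyp51 and Itga8 were chosen after their values were seen. Some of the genes chosen for naming and 1 gene list are not reported here, and counts over all genes or lists include them.

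Bradykinin replicate 3 stood apart, so the planned fit without it was extended, after the data had been seen, to lists, annotation terms (Fisher's exact test, one-sided, 6833 terms of 10 to 500 tested genes, with the 12536 tested genes as background, SciPy 1.17.1) and further alternatives. Those terms are the GO and KEGG entries that the deposited table pairs with 15648 genes. Alternatives fixed in advance were RLE size factors, library totals, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 libraries, each library left out, the replicate block, and 2 other set tests. Added after the data were seen were limma-voom with library quality weights and a loess offset on gene span. The quality weights were 0.0517 for bradykinin replicate 3 and 1.31 to 2.81 for the others.

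The steps were tested on simulated counts with the real means, library sizes and dispersions, in which 100 genes changed by 1.5-fold and 100 by 2-fold. With 6 libraries and 12413 genes, edgeR recovered 5 of the 1.5-fold and 50 of the 2-fold changes with 3 false calls, and DESeq2 25 and 76 with 23 false calls. With 5 libraries and 12536 genes, edgeR recovered 71 and 81 with 14 false calls. In both, camera called the 1 list that had been changed and 0 others. Genes were drawn independently and no library was made to stand apart. The simulation therefore does not test list calls where genes move together, or recovery with an outlying library. Plots were drawn with matplotlib 3.10.9.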

Results

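Polyadenylated RNA was sequenced from primary rat nucleus pulposus cells, the cells of the gel-like core of the intervertebral disc. The cells were left untreated (control, n = 3 libraries) or given 10 µM bradykinin (n = 3 libraries), a vasoactive peptide that signals through the receptors B1 and B2. The treated samples are titled B2R, and their treatment label, which names bradykinin, was followed. Total counts per library were 12883067, 14224447 and 14604917 in the bradykinin group and 15462764, 14252966 and 14819043 in the control group. The series poses the question of how bradykinin alters gene expression in these cells, with senescence and matrix turnover as its focus. Levels are given as CPM, counts scaled to a common library size, mean ± SD over 3 libraries unless other libraries are named, and log2 fold changes ± SE are bradykinin over control. The labels do not say whether the replicates came from separate animals or cultures. The p-values of single genes therefore measure the spread between these libraries, which may be technical. Those of camera set a list's genes against the other genes, and those of annotation terms count genes. An edgeR p adjusted over a list alone is not corrected for the number of lists, so passing there is weaker than passing over all genes.

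No single gene passed the test between 3 bradykinin and 3 control libraries, but several gene groups fixed in advance shifted. Cell division and DNA replication genes were higher with bradykinin (median log2 fold changes 0.27 and 0.32), with 25 of 26 and 27 of 27 measured members on the higher side. Glycolytic and hypoxia-responsive genes (median 0.25) and NF-kB-linked inflammatory genes (median 0.28) were also higher, and contractile genes (median -0.15) were lower. Without bradykinin replicate 3 the glycolytic and NF-kB medians were smaller, 0.13 and 0.16. These 5 lists were called by camera with a preset correlation, and none was with an estimated correlation (adjusted p = 0.413 for each). The smallest p of any gene was that of Col15a1, a basement membrane collagen, at 152 ± 20.01 CPM with bradykinin and 67.4 ± 4.37 CPM in controls. Without bradykinin replicate 3, a library that stood apart from the other 5, 388 genes changed. Among them was Acan, the large aggregating proteoglycan of the disc, which rose by a log2 fold change of 0.95 ± 0.04. In all 6 libraries its change was 0.74 ± 0.19 and did not pass (edgeR adjusted p = 0.626). Replicate 3, at 301 CPM, lay nearer the controls (262 ± 8.31 CPM) than replicates 1 and 2 (498 and 511 CPM).

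By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 12413 genes had an adjusted p of 0.05 or less, and 849 had an unadjusted p under 0.05. Limma-voom also called 0 genes, with 848 at an unadjusted p under 0.05. DESeq2 called 44 genes, 25 higher and 19 lower, of which 15 differed by 2-fold or more. All 44 were called in the same direction by edgeR without bradykinin replicate 3. That edgeR fit uses 5 of the same libraries, so the overlap was partly fixed in advance and is no independent support. In that fit of 5 libraries, 244 of 12536 genes rose and 144 fell, and 21 of them changed by 2-fold or more. Scaling by library totals alone turned the split of these 5 libraries to 162 higher and 185 lower. Leaving out control replicate 1, 2 or 3 as well left 145, 138 or 209 genes.

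**Figure D1:**
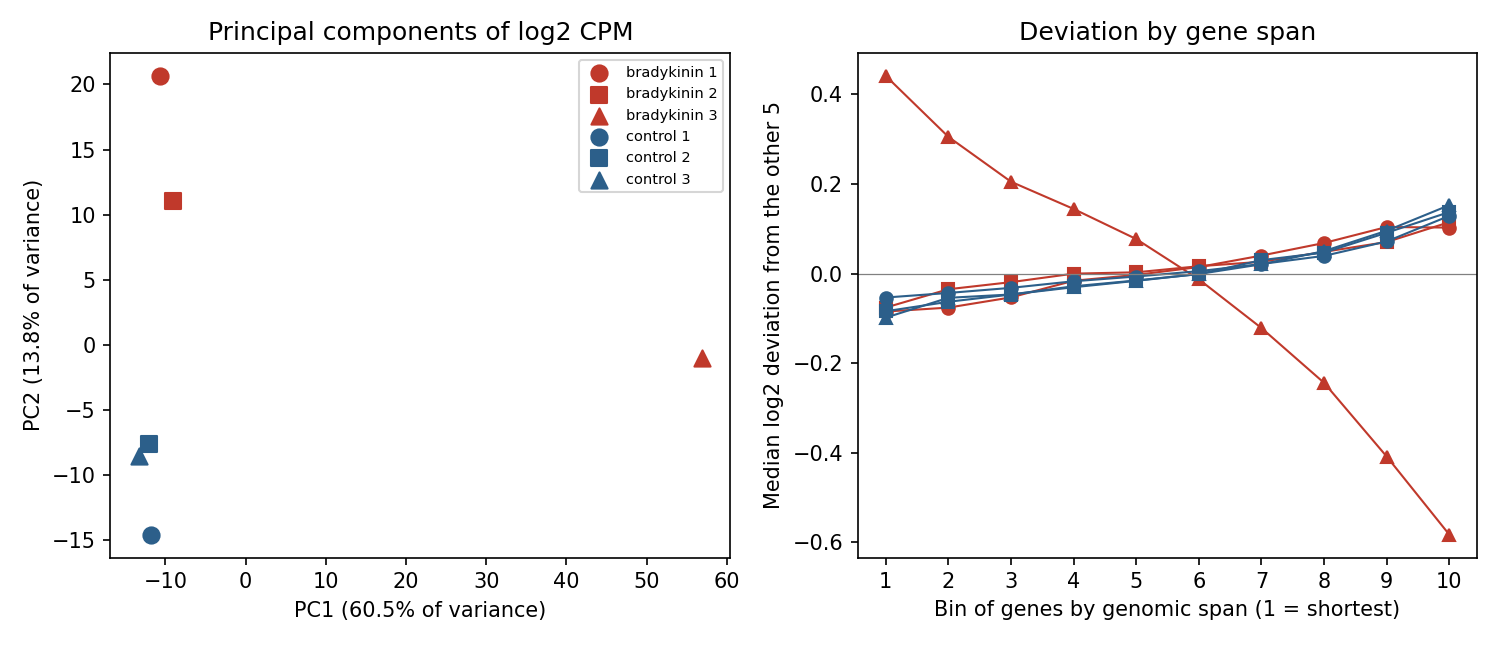
Left, the first and second principal components of log2 CPM for the 6 libraries; right, the median log2 deviation of each library from the mean of the other 5 (y axis) for genes in 10 equal bins of genomic span (x axis, 1 is shortest). Bradykinin replicate 3 lies at 56.9 on the first component, which holds 60.5% of the variance, and its deviation falls from 0.44 in the bin of shortest genes to -0.58 in that of the longest.

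Bradykinin replicate 3 stood apart from the other libraries across genes. Its Spearman correlations with the other libraries, across genes, were 0.960 to 0.963, while pairs among the other 5 reached 0.996. The SD across genes of its log2 deviation from the other 5 libraries was 0.59, against 0.24 to 0.28 in the others. Counts of bradykinin replicates 1 and 2 differed by a chi-square of 5.22 per degree of freedom, and pairs with replicate 3 by 76.4 and 79.9. Pairs of controls gave 2.30 to 3.74. No pair of replicates agreed within sampling noise. The common biological coefficient of variation was 0.168 with all 6 libraries and 0.0537 without replicate 3.

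Both bradykinin receptors were expressed, Bdkrb2 at a higher level than Bdkrb1, and neither passed the test. Bdkrb1, the inducible B1 receptor, was at 4.56 ± 0.329 CPM with bradykinin and 3.68 ± 0.472 in controls (log2 fold change 0.31 ± 0.18, edgeR adjusted p = 0.737). Bdkrb2, the constitutive B2 receptor, was at 15.7 ± 3.45 and 18.4 ± 0.959 CPM (-0.23 ± 0.18, adjusted p = 0.737; -0.06 ± 0.10 without bradykinin replicate 3). Among the 9 measured members of the kinin system list, 0 passed over all genes or when adjusted over the list alone. Mme, which encodes the bradykinin-degrading enzyme neprilysin, was at 23.0 ± 5.48 CPM with bradykinin and 31.8 ± 1.84 in controls. The list as a whole did not shift (camera adjusted p = 0.399).

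The 10 genes with the smallest p in all 6 libraries had edgeR adjusted p from 0.233 to 0.437. Besides Col15a1 (log2 fold change 1.17 ± 0.12, adjusted p = 0.233), those on the higher side included Cited1, a transcriptional coregulator (2.45 ± 0.36), Hspb7, a small heat shock protein (0.77 ± 0.13), and a gene without a symbol, ENSRNOG00000003209 (1.07 ± 0.14). On the lower side stood, among others, Car3, a carbonic anhydrase used as a nucleus pulposus marker (-1.34 ± 0.18), Sema3a, a repulsive axon guidance cue (-1.40 ± 0.23), Akap12, a kinase-anchoring scaffold (-0.75 ± 0.13), and Scara5, a ferritin receptor (-1.18 ± 0.20). Cers1, a ceramide synthase, had 3 counts in the bradykinin group and 55 in controls, a control to bradykinin ratio of 17.3 (exact 95% interval 5.60 to 86.2, counting error only). All 10 genes were called in the 5 libraries without bradykinin replicate 3, in the same direction. Those libraries are among the 6 from which the genes were picked, so this was partly fixed in advance. Akap12 was the most abundant of the 10 genes, at 822 ± 116 CPM with bradykinin and 1384 ± 60.8 in controls.

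**Figure D2:**
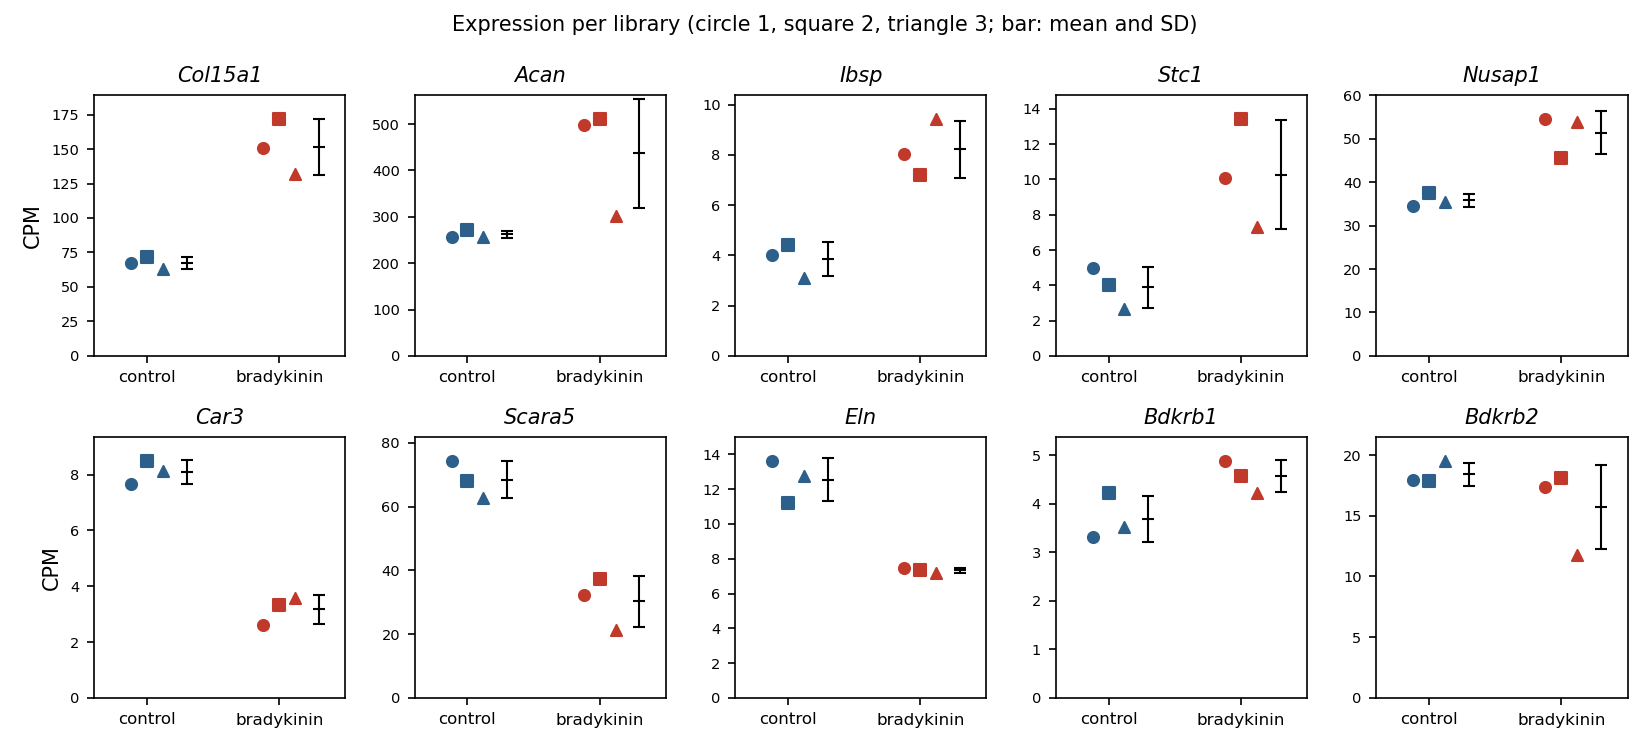
CPM (y axis, from 0) of 10 genes in each control and bradykinin library; circles, squares and triangles are replicates 1, 2 and 3, and bars give the mean and SD of 3 libraries. Col15a1 lies between 132 and 172 CPM in bradykinin libraries and between 63.0 and 71.7 in controls, and Acan in bradykinin replicate 3 (301 CPM) lies nearer the controls than replicates 1 and 2 (498 and 511 CPM).

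In the 5 libraries, the largest rises among well-expressed genes that have a symbol and do not overlap between groups were in Ptbp2, a neuronal splicing regulator (log2 fold change 1.86 ± 0.10), Zfp950 (1.82 ± 0.45), Stc1, a secreted calcium and phosphate regulator (1.60 ± 0.22), Rasl12 (1.45 ± 0.18) and Col15a1 (1.26 ± 0.07). Cep41, a ciliary protein (1.17 ± 0.28), Klhl41, a sarcomere-associated protein (1.15 ± 0.18), Itga7, a laminin receptor subunit (1.00 ± 0.09), Ibsp, bone sialoprotein (0.98 ± 0.19), and Acan followed. Ptbp2 was at 63.1, 50.6 and 15.5 CPM in bradykinin replicates 1, 2 and 3 and at 15.7 ± 0.657 in controls. Cep41 and Zfp950 were led by bradykinin replicate 1, with Cep41 at 49.7, 18.96 and 6.31 CPM in replicates 1, 2 and 3 and Zfp950 at 13.2, 3.20 and 2.08. Among the 10 largest falls by the same limits were those in Car3 (-1.44 ± 0.19), Islr (-1.07 ± 0.21), Gprin3 (-0.98 ± 0.19), Scara5 (-0.98 ± 0.09) and Bmp3, a bone morphogenetic protein (-0.92 ± 0.18). Ccn3, a matricellular protein (-0.90 ± 0.18), Crabp1, a retinoic acid binding protein (-0.79 ± 0.20), Serhl2 (-0.79 ± 0.18) and Eln, elastin (-0.76 ± 0.14), were also among them. Crabp1 and Serhl2 in bradykinin replicate 3 (8.46 and 8.40 CPM) were above their control means of 7.64 and 8.07 CPM.

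By edgeR, no gene of the matrix lists passed over all genes in the 6 libraries, and without bradykinin replicate 3 some rose and others fell. Of 14 measured cartilage-type matrix genes, 0 passed in the 6 libraries, and the list did not shift (camera adjusted p = 0.246). Acan was at 437 ± 117 CPM with bradykinin and 262 ± 8.31 in controls (0.74 ± 0.19, edgeR adjusted p = 0.626), and Sox9, the master regulator of chondrocyte genes, at 21.9 ± 6.33 and 22.9 ± 1.58 CPM (adjusted p = 0.915). The fibrillar collagen gene Col11a1 stood at 1807 ± 303 CPM with bradykinin and 2300 ± 68.1 in controls (-0.35 ± 0.14, adjusted p = 0.714). Col27a1 and Col11a2 had log2 fold changes of -0.39 ± 0.14 and -0.52 ± 0.29 and did not pass. In the 5 libraries Acan rose and Col11a1 fell (-0.22 ± 0.04), and the other 13 measured members, Col11a2 (-0.34 ± 0.34) among them, did not pass. Col2a1, the main cartilage collagen, had 0 to 2 counts per library and was not tested.

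Of 25 fibrous matrix genes, 0 passed over all genes, and Eln was the only member past the threshold when adjusted over the list alone (-0.78 ± 0.14, adjusted p = 0.0149 over the list). Col14a1 had a log2 fold change of -0.52 ± 0.15, and Col6a2 and Dcn 0.20 ± 0.10 and 0.19 ± 0.10 (Dcn 0.12 ± 0.05 without bradykinin replicate 3). The median of the list was 0.002 and its mean -0.05, on either side of 0 (camera direction lower, adjusted p = 0.449). In the 5 libraries the list shifted upward (camera adjusted p = 0.0188; adjusted p = 0.936 with an estimated correlation; 4.9e-04 to 0.936 over the alternatives of that fit), a call lost when control replicate 3 was left out as well (0.105), or bradykinin replicate 2 (0.555), which leaves 1 bradykinin library, assumed to vary like the controls. There, 9 members rose, Col6a2 among them, and 2, Eln and Col14a1, fell. The median deviation of these genes from the mean of all libraries was -0.31 in bradykinin replicate 3 and 0.05 and 0.19 in replicates 1 and 2.

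Among 21 measured matrix-degrading enzymes, 0 passed over all genes or over the list alone, and the list did not shift (camera adjusted p = 0.137), although it was called lower with the gene span offset, an alternative chosen after the data were seen (adjusted p = 0.0189). The stromelysin gene Mmp3 was at 194 ± 28.4 CPM with bradykinin and 207 ± 2.11 in controls (adjusted p = 0.776), and the collagenase gene Mmp13 at 107 ± 9.85 and 127 ± 10.2 CPM (adjusted p = 0.737). The aggrecanase genes Adamts4 (4.61 ± 0.664 and 5.30 ± 0.493 CPM) and Adamts5 (63.9 ± 25.4 and 74.4 ± 1.56 CPM) had adjusted p of 0.746 and 0.781. Adamts9 and Adamts15 had log2 fold changes of -1.07 ± 0.37 and -0.64 ± 0.19, Mmp14 -0.23 ± 0.09 and Htra1 0.36 ± 0.15 (0.19 ± 0.06 without bradykinin replicate 3). Without bradykinin replicate 3, 3 members fell, Mmp3 (-0.22 ± 0.05), Adamts9 (-0.69 ± 0.14) and Adamts15 (-0.46 ± 0.11). Adamts12, named after its values were seen, rose there (0.26 ± 0.05, against 0.02 in the 6 libraries). In replicate 3 itself, however, Mmp3 was at 226 CPM, above its control mean of 207 CPM. Adamts12 was at 70.2 CPM in that library, below its control mean of 108 CPM, while Adamts9 and Adamts15 were below theirs as well. Timp1, an inhibitor of these enzymes, was at 258 ± 81.5 CPM with bradykinin, with 352 CPM in replicate 3, and 188 ± 2.55 in controls. None of the 4 measured inhibitors passed over all genes in either fit, while Timp1 rose in the 5 libraries when adjusted over the list alone (0.17 ± 0.04, adjusted p = 0.0087 over the list).

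The senescence core list, 15 measured cell cycle inhibitors and nuclear proteins linked to senescence, did not shift (camera adjusted p = 0.315). Cdkn1a, which encodes p21, was at 35.7 ± 2.29 CPM with bradykinin and 30.6 ± 1.33 in controls (0.22 ± 0.10, edgeR adjusted p = 0.737). Cdkn2a, which encodes p16 and ARF, was at 22.5 ± 7.78 and 20.9 ± 0.909 CPM (adjusted p = 0.862), with 31.4 CPM in bradykinin replicate 3 and 16.9 and 19.3 in replicates 1 and 2. Cdkn2b, which encodes the inhibitor p15, was the 1 member past the threshold when adjusted over the list alone (-0.68 ± 0.14, adjusted p = 0.0233 over the list), and it fell in the 5 libraries (-0.76 ± 0.11). Cdkn2c, which encodes p18, rose in the 5 libraries (0.35 ± 0.08). Lmnb1, the lamin that is lost in senescent cells, and Hmgb2 had log2 fold changes of 0.27 ± 0.10 and 0.61 ± 0.26 in the 6 libraries and did not pass, and without bradykinin replicate 3 Hmgb2 was at 0.23 ± 0.09.

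Secreted factors of the senescence-associated kind split by gene. Of 35 measured members, 0 passed over all genes, while 4 higher and 1 lower passed when adjusted over the list alone. Those higher included Igfbp3 (0.60 ± 0.11), Fgf7 (0.42 ± 0.09) and Serpine2 (0.53 ± 0.13). The one lower was the chemokine gene Cxcl12 (212 ± 11.01 and 303 ± 4.87 CPM, -0.52 ± 0.09). Over the 5 libraries, 5 members rose, Igfbp3, Fgf7, Serpine2 and Spp1 among them, and 2, Cxcl12 and Mmp3, fell. In bradykinin replicate 3, Cxcl12 was also below its control mean, but Mmp3, at 226 CPM, was above its control mean of 207 CPM. Il6 had 1 to 9 counts per library and Il1b 0 in all 6, which allows up to 3 counts in each, and neither was tested. The list as a whole did not shift (camera adjusted p = 0.137).

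The smallest p among the lists came from proliferation genes. The cell division list was higher with bradykinin (camera adjusted p = 4.3e-10; adjusted p = 0.413 with an estimated correlation), as was the DNA replication list (camera adjusted p = 1.8e-11; adjusted p = 0.413 with an estimated correlation). Adjusted over the list alone, 2 of 26 cell division genes passed, the spindle protein gene Nusap1 (0.52 ± 0.11) and the mitotic kinase gene Aurkb (0.49 ± 0.10). In DNA replication 3 of 27 passed, the ribonucleotide reductase gene Rrm2 (0.46 ± 0.09), the cyclin gene Ccne2 (0.61 ± 0.14) and the flap endonuclease gene Fen1 (0.49 ± 0.11). Aurka, Ccna2 and Ccne1 had log2 fold changes of 0.47 ± 0.13, 0.36 ± 0.11 and 0.65 ± 0.20. Rrm2 was at 186 ± 6.76 CPM with bradykinin and 135 ± 7.07 in controls. In the 5 libraries 10 cell division genes and 7 replication genes rose and 0 fell, and 23 and 21 rose when adjusted over the list alone. The median deviation of the cell division genes was 0.23, 0.05 and 0.21 in bradykinin replicates 1, 2 and 3, and -0.27, -0.13 and -0.10 in controls.

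**Figure D3:**
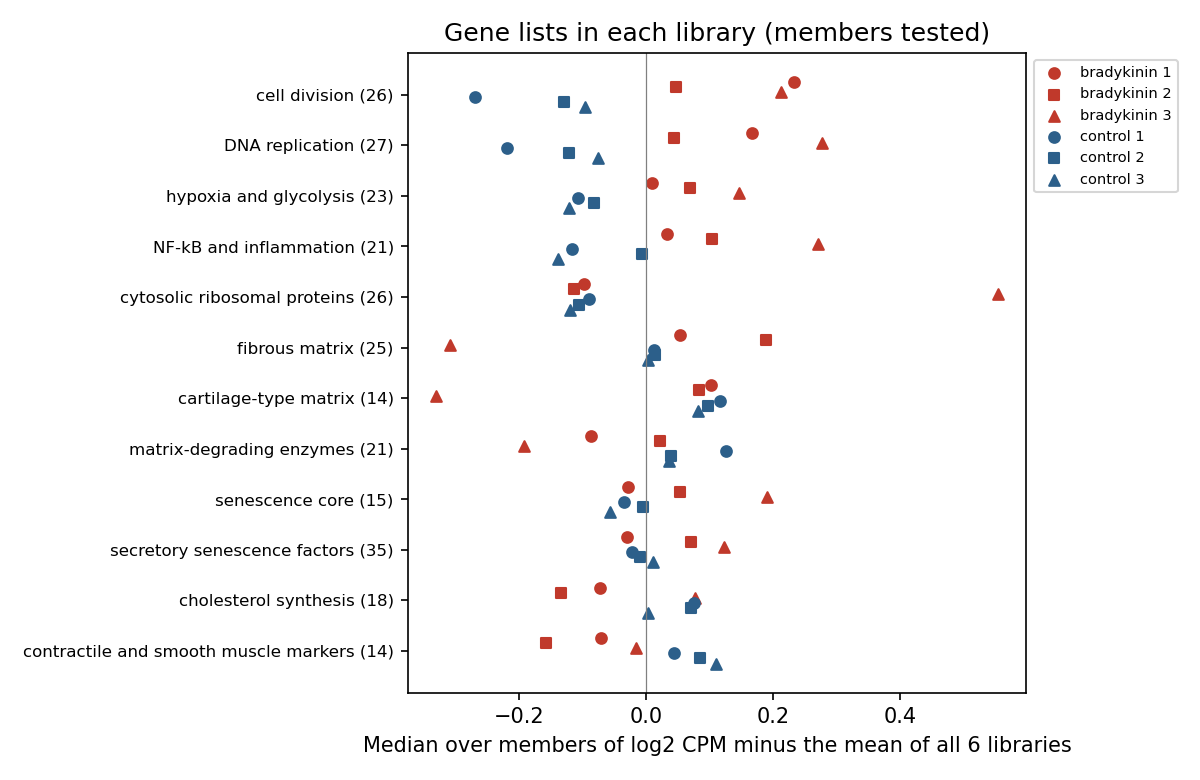
Median over the measured members of each fixed gene list (rows, with the number of members) of log2 CPM minus the mean of all 6 libraries (x axis); each point is a library, with circles, squares and triangles for replicates 1, 2 and 3. The cell division medians lie between 0.05 and 0.23 in bradykinin libraries and between -0.27 and -0.10 in controls, while the ribosomal protein median is 0.55 in bradykinin replicate 3 and between -0.12 and -0.09 elsewhere.

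Inflammatory genes under NF-kB control were higher as a group (camera adjusted p = 0.0034; adjusted p = 0.413 with an estimated correlation). Ptgs2, which encodes the inducible cyclooxygenase, was at 200 ± 12.7 CPM with bradykinin and 137 ± 9.74 in controls (0.54 ± 0.10) and was the 1 of 21 members to pass over the list alone. Ptgs2 also rose in the 5 libraries, as the only member. Bcl3 (0.66 ± 0.25), Ccl2 (0.42 ± 0.16) and Tnfaip6 (0.40 ± 0.16, and 0.23 ± 0.11 without bradykinin replicate 3) did not pass. Of 32 immediate-early and ERK feedback genes, Junb passed over the list alone (97.7 ± 4.44 and 69.0 ± 5.86 CPM, 0.50 ± 0.10), and the list did not shift (camera adjusted p = 0.763). Egr3 and Egr2 had log2 fold changes of -0.78 ± 0.31 and -0.38 ± 0.18. The interferon response list did not shift (camera adjusted p = 0.137) but was called lower with the gene span offset (0.0317).

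Metabolic groups moved in opposite directions. Hypoxia and glycolysis genes were higher (19 of 23 positive, camera adjusted p = 2.5e-04; adjusted p = 0.413 with an estimated correlation), with the glycolytic enzyme genes Tpi1 (0.31 ± 0.09), Pgam1 (0.35 ± 0.12) and Ldha (0.36 ± 0.12) and the kinase gene Pdk1 (0.25 ± 0.10) at the smallest p. Over the 5 libraries, Tpi1, Pgam1 (0.22 ± 0.04), Ldha (0.23 ± 0.04) and, named after their values were seen, Pgk1 and Pkm rose, and 0 members fell. Cholesterol synthesis genes were lower (3 of 18 positive, camera adjusted p = 0.032; adjusted p = 0.600 with an estimated correlation). The cholesterol call was lost in 8 of 14 alternatives, among them the fits without bradykinin replicate 1 or 2 (adjusted p = 0.192 and 0.236) and without control replicate 1 or 2 (0.073 and 0.139), over a range of 2.5e-04 to 0.600. Their median deviation was -0.07 and -0.13 in bradykinin replicates 1 and 2 but 0.08 in replicate 3, which was not below the controls (0.004 to 0.08). Sc5d (-0.23 ± 0.10), Lss (-0.27 ± 0.13), Insig1 (-0.21 ± 0.10) and Dhcr7 (-0.32 ± 0.19) had the smallest p, and Insig1, Dhcr7 and, named after its values were seen, Cyp51 fell in the 5 libraries, though Cyp51 in replicate 3 was at 220 CPM, above the control mean of 197 CPM.

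Contractile and smooth muscle genes were lower as a group (camera adjusted p = 0.013; adjusted p = 0.413 with an estimated correlation), with 4 of 14 members positive. The call was lost without bradykinin replicate 1 (adjusted p = 0.069) or 2 (0.114), over a range of 2.9e-04 to 0.413 in 14 alternatives. Adjusted over the list alone, the smooth muscle actin gene Actg2 (-0.54 ± 0.13), the myosin gene Myh11 (-0.41 ± 0.11) and the myosin kinase gene Mylk (-0.46 ± 0.12) were lower, and Des, which encodes the intermediate filament protein desmin, was higher (0.62 ± 0.14). Over the 5 libraries, 7 members fell, and Des and, named after its values were seen, Itga8 rose. Acta2 and Tagln, named after their values were seen, fell there (-0.56 ± 0.04 and -0.40 ± 0.04). In bradykinin replicate 3, however, they stood at 1420 and 1538 CPM, against control means of 1463 ± 60.8 and 1457 ± 35.1. Itga8 in that library was at 73.3 CPM, below its control mean of 102 ± 2.44.

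The lists of nucleus pulposus, annulus and tendon, and osteogenic markers did not shift, and in the 6 libraries 0 of their members passed over all genes. Of 13 nucleus pulposus and notochord markers (camera adjusted p = 0.339, direction lower, with a median of 0.005 and a mean of -0.10), Car3 alone passed over the list alone, at 3.17 ± 0.510 CPM with bradykinin and 8.09 ± 0.416 in controls. Pax1, Lgals3 and Ncam1 had log2 fold changes of -0.30 ± 0.11, 0.40 ± 0.17 and -0.48 ± 0.24. In the 5 libraries Car3 and Ncam1 (-0.22 ± 0.05) fell, and Lgals3 (0.18 ± 0.05) did not pass. Of 13 annulus and tendon markers (camera adjusted p = 0.975, direction lower, with a median of 0.008 and a mean of 0.01), Thbs4, a matrix glycoprotein, passed over the list alone (2616 ± 318 and 1618 ± 87.3 CPM, 0.69 ± 0.12). Pdgfrb had a log2 fold change of -0.45 ± 0.16. Without bradykinin replicate 3, Thbs4 rose and 2 members fell, Pdgfrb (-0.28 ± 0.06) among them. Of 6 osteogenic markers (camera adjusted p = 0.251), Ibsp passed over the list alone (8.22 ± 1.13 and 3.85 ± 0.674 CPM, 1.09 ± 0.20), and Spp1, which encodes osteopontin, was at 3697 ± 1064 and 2622 ± 57.0 CPM. Both rose in the 5 libraries, Spp1 by 0.24 ± 0.05 against 0.50 ± 0.19 in the 6.

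Some groups differed mainly in bradykinin replicate 3. Cytosolic ribosomal protein genes were higher over the 6 libraries (26 of 26 positive, camera adjusted p = 2.5e-04; adjusted p = 0.640 with an estimated correlation), and without replicate 3 the adjusted p was 0.909, within a range of 6.1e-06 to 0.909 over 14 alternatives. Their median deviation was 0.55 in replicate 3 and -0.10 and -0.11 in replicates 1 and 2. The mitochondrially encoded (camera adjusted p = 0.246; called lower without bradykinin replicate 1, 0.0143), oxidative stress (0.427) and unfolded protein (0.137) lists did not shift, and their median deviations in replicate 3 were -0.31, 0.33 and 0.19. The other libraries lay between -0.09 and 0.28 for the mitochondrially encoded genes, with 0.28 in bradykinin replicate 1, so that list did not differ mainly in replicate 3. Of 19 FoxO targets (camera adjusted p = 0.232; called lower with the gene span offset, 0.0165), Irs1, an insulin receptor substrate, passed over the list alone (38.5 ± 8.64 and 64.1 ± 0.889 CPM, -0.74 ± 0.17). Summed CPM of marker lists of other cell types in replicate 3 and, on average, in the other 5 libraries were 15.6 and 11.1 for leukocytes, 41.6 and 30.5 for endothelium, 11.3 and 8.81 for skeletal muscle, 41.3 and 36.6 for neural cells and 0.195 and 0.139 for erythroid cells. In those lists 0 genes passed in the 6 libraries, and S100b fell in the 5 libraries (-0.53 ± 0.12). In replicate 3, however, S100b was at 32.4 CPM, near its control mean of 32.0 CPM, and made up most of the neural sum.

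With 0 changed genes in the 6 libraries, no annotation term could be enriched. Among the genes changed in the 5 libraries, 548 terms of the deposited annotation were enriched by Fisher's exact test (one-sided), 371 among the genes that rose and 177 among those that fell. Chromosome segregation held 31 rising genes where 4.52 were expected (adjusted p = 2.0e-13), and DNA replication 21 where 3.72 were expected (9.6e-08). Collagen-containing extracellular matrix held 23 rising genes where 3.00 were expected (8.0e-11), and basement membrane 15 where 1.58 were expected (3.1e-08). Falling genes were enriched for receptor ligand activity, with 13 where 1.63 were expected (4.4e-06), growth factor activity, with 8 where 0.839 were expected (3.8e-04), and extracellular matrix, with 15 where 2.61 were expected (2.0e-05). Extracellular matrix was thus enriched on both sides, with 26 rising genes where 4.42 were expected. When changed genes were restricted to those of 2-fold or more, 0 terms were enriched. Fisher's exact test treats genes as independent, so genes that move together can make these p-values too small. Nor do they measure spread between libraries. In the same 5 libraries, the cell division and DNA replication lists each had a camera adjusted p of 0.579 with an estimated correlation.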

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

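The fits with quality weights and with the gene span offset, and all alternatives of the 5-library fit, were chosen after the data were seen. The count of 0 changed genes stayed at 0 under RLE size factors, library totals, limma-voom, either filter and the replicate block (591 genes at an unadjusted p under 0.05). No sign of pairing by replicate number was seen: deviations of same-numbered libraries correlated at -0.09, -0.02 and -0.05, and no library correlated best with its own number. Replicate 3 weighs on the deviations of all bradykinin libraries, since these are taken from the group mean, so a pairing is not excluded. DESeq2 gave 44 genes (15 with 2-fold or more), voom with quality weights 260 (20), and the span offset 1, Col15a1 (1). Leaving out each library gave 0 to 388 genes (0 to 21 with 2-fold or more), with 388 and 21 without bradykinin replicate 3 and 0 in the other 5 fits. That fit had 548 enriched terms. Its 388 genes became 681 with no filter, all 388 among them, and 138 to 333 with a further library left out. In that fit, leaving out bradykinin replicate 1 or 2 (300 and 333 genes) leaves 1 bradykinin library, which is assumed to vary like the controls that alone give the spread; without a control the counts were 138 to 209. The count of 7 called lists went to 0 with an estimated correlation and 0 with fry; in the 5 libraries it went from 7 to 0 and 2. With the span offset 10 lists were called, the 7 and, all lower, matrix-degrading enzymes (0.0189), interferon response (0.0317) and FoxO targets (0.0165). Leaving out each library gave 5 to 7 called lists in either fit, but not the same ones. From the 6 libraries, the contractile and cholesterol calls were lost without bradykinin replicate 1 or 2, the cholesterol call without control replicate 1 or 2 and the ribosomal call without bradykinin replicate 3, while the mitochondrially encoded list was gained without bradykinin replicate 1 (0.0143) and fibrous matrix without replicate 3 (0.0188). From the 5, the NF-kB call was lost without control replicate 1 (0.0505) or 3 (0.0776) and the fibrous matrix call without control replicate 3 (0.105); with the 1 bradykinin library left without replicate 2, both were lost (0.106 and 0.555).

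None of the named genes passed in the 6 libraries. In the same direction, 68 passed without bradykinin replicate 3, 55 with quality weights, 26 with DESeq2 and 1 with the span offset. Some were named because they passed without replicate 3, or after their values were seen, so the 68 were partly fixed in advance. The same holds in part for the 55, since the quality weight of replicate 3 was only 0.0517. Log2 fold changes turned sign when single libraries were left out for Sox9 (-0.28 to 0.14), Adamts5 (-0.47 to 0.074), Cdkn2a (-0.21 to 0.28), Cep41 (-0.27 to 1.17), Adamts12 (-0.12 to 0.26) and Itga8 (-0.067 to 0.27), for Adamts12 with limma-voom (-0.037) and the replicate block (-0.032), and with quality weights for Sox9 (0.095), Adamts5 (0.046) and Cdkn2a (-0.19). Among lists that were not called, directions turned with single libraries left out, with camera adjusted p of 0.0188 to 0.615 (fibrous matrix), 0.372 to 0.984 (immediate-early), 0.507 to 0.972 (annulus and tendon), 0.260 to 0.800 (oxidative stress), 0.0561 to 0.999 (unfolded protein) and 0.0143 to 0.972 (mitochondrially encoded). The immediate-early genes also turned with the span offset (0.446), and the annulus and tendon genes with no filter (0.916) and fry (0.846). Apart from the outlying replicate, whose removal cuts the biological coefficient of variation from 0.168 to 0.0537, the cause was not tested. Genes such as Il6, Il1b and Col2a1 had too few counts to test in these libraries.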

Other observations

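The tests on gene span in bradykinin replicate 3 and on markers of low level, and the extension to 5 libraries were chosen after the result was seen. Matrix genes led the most abundant transcripts in both groups: Col1a1 stood at 42935 ± 5537 CPM with bradykinin and 42683 ± 1667 in controls, Thbs1 at 27099 ± 6551 and 27614 ± 336, and Col1a2 at 24507 ± 2372 and 23461 ± 625 (n = 3 each). Fn1 was at 21455 ± 9268 and 26880 ± 313 CPM. Angiogenesis terms, which the fixed lists did not cover, were enriched among genes that rose in the 5 libraries (30 genes where 6.25 were expected, adjusted p = 1.1e-09), as was wound healing (21 where 4.67 were expected, 4.4e-06). Vasculature development was enriched among rising genes (37 where 9.25 were expected, 6.2e-10) and among falling genes (19 where 5.46 were expected, 4.2e-04). These p-values, too, come from Fisher's exact test, which treats genes as independent and does not measure spread between libraries.

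Bradykinin replicate 3 stood apart from the other 5 libraries. A shift of signal from long to short genes, as RNA quality or library preparation may give, was tested by the correlation across genes of its deviation with genomic span, which was -0.51 (0.23 to 0.33 in the other libraries). Removing that trend lowered the SD of its deviation only from 0.59 to 0.51, against 0.23 to 0.27 in the others, so the trend is a candidate for part of the pattern and not the whole. Leukocytes and endothelial, erythroid, neural or skeletal muscle cells are argued against as the cause of the whole pattern. The summed CPM of their markers was 1.26 times the mean of the other libraries, below the 1.5 set in advance but above the highest other library (1.06 times). Of that sum 76.3% came from 3 markers also expressed in the other libraries, which would hide a small share of such cells. The 25 of 36 markers under 1 CPM in each of the other libraries summed to 2.41 CPM in replicate 3, against a mean of 2.19 and a highest of 2.83 in the others. A small share stays open, but dilution by it would not lower genes by 1 log2 unit, and 979 genes lay at least that far below the controls. Cells that these markers do not cover, such as annulus fibroblasts, were not tested as a cause and stay open. A stronger form of the response in replicates 1 and 2 is argued against as well. The 1194 genes at least 1 log2 unit from the controls in replicate 3 changed little in its direction in replicates 1 and 2. Their median change there was 0.080 (95% bootstrap interval 0.065 to 0.092, over genes and not libraries). Both changes are taken against the same controls, which by itself can raise this median. A different response of that culture to bradykinin, or a different culture, stays open and was not tested.

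The 388 genes that changed without bradykinin replicate 3 are a second pattern. A shift by gene span is argued against as their cause, since 94.7% of the 374 with a known span were still called after the span offset. Of the 388, 70.4% had the same sign in replicate 3 against the controls. The highest of 20 simulations with no effect in replicate 3 was 58.7%, and the highest of 1000 reassignments among genes of like span and level was 58.0%. Median changes were 0.36 in replicates 1 and 2 and 0.33 in replicate 3. The simulations drew genes independently with new, simulated controls, and the reassignments moved genes singly. Genes that move together can widen both ranges, so neither limit is firm. A response that replicate 3 shares in part stays a hypothesis that these values allow. Part of the excess may also come from the real controls, which both comparisons share and which were too few to split. The 10 splits of 5 libraries into 2 and 3 are too few for a share under 0.05; the real split alone (1 of 10) gave as many genes, 388, and the highest other gave 1.

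For the 6 libraries, the real split gave 0 changed genes and the highest of the other splits gave 0. Any split reaches a count of 0, so that 10 of 10 gave as many says nothing about chance, and 10 splits are in any case too few for a share under 0.05.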
